A study of Homo sapiens with 9 samples.

How the data were processed

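RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line, carrying a lentiviral short hairpin RNA. The hairpin was a scrambled control (shScr) or 1 of 2 hairpins against CTDP1 (shCTDP1-#1 and shCTDP1-#2). CTDP1 encodes a phosphatase that removes phosphate from the C-terminal domain of RNA polymerase II. Each group held 3 libraries, so the series held 9. Per the labels' protocols, the virus was produced in 293FT cells, infected cells were selected with puromycin, and libraries were made from total RNA with a TruSeq kit, which does not mark the strand of origin. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

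Per the submitters' processing notes, STAR, RSEM and the hg19 build were used; no versions are given in the sources used here. The authors deposited 1 file per library with a value for each of 57773 genomic intervals. The values are taken as TPM, transcript abundance scaled to the same total in every library, because the values the authors deposited sum to that unit's fixed total in each library and RSEM reports that unit. They carry 2 decimals. TPM keeps no total count, so the depth of each library is unknown, and no counting interval or detection floor is given. All 9 files listed the same intervals, in differing row order, and were joined on their coordinates; 2 files ended in a blank row. The 2246 rows that shared an interval with another row were left out, which took between 0.355% and 0.391% of the TPM of a library. This left 55527 intervals, of which 2816 lay on alternate or unplaced sequences. No pair of files was identical in every interval.

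The files do not pair the intervals with gene names or identifiers. The annotation at hand, GENCODE v29, is of another build (GRCh38). An exploratory attempt to name intervals by matching spans and local offsets to GENCODE v29 was dropped, because it amounts to converting coordinates between builds. Values of genes under those names had been seen by then, but no value given here uses them. Nuclear intervals are described by hg19 position alone. CTDP1 itself is not reported, so the level of the targeted gene in each library, the usual check of a knockdown, was not analysed here. The same holds for all but 1 of the gene lists fixed before the data were examined. The exception is the mitochondrial sequence, which is the same in both annotations: all 37 mitochondrial intervals were identical at both ends to GENCODE v29 without any shift, and their names were taken from it. That identity also showed that the starts in the files count from 1.

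Intervals with at least 1 TPM in at least 3 libraries were tested, 15011 in all. log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (trend and robust options, statmod 1.5.0), with all 9 libraries in one fit of group means and 6 residual degrees of freedom. The Benjamini-Hochberg adjusted p had to be under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of intervals at low level. The design fixed before the data were examined named count-based tests, with this limma fit as the choice for files that hold TPM. The planned count-based tests, their normalization factors and the comparison of rounded with unrounded counts were not run.

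The rule for the printed intervals was fixed beforehand for genes: past the adjusted p of 0.05 with both hairpins in the same direction, a mean of at least 5 TPM, and all knockdown libraries on the same side of all shScr libraries, ranked by the smaller of both absolute log2 changes. Since the intervals have no names, only the first 2 in each direction are printed, the X and Y chromosomes are left out, and the parts of the rule that need a symbol were not applied. The 13 mitochondrially encoded mRNAs were tested as a list with camera (preset correlation 0.01), with an estimated correlation, and with fry; adjustment over a single list leaves its p unchanged, so the adjusted p given for it is the p of camera, limma's set test. Both comparisons with shScr share its 3 libraries. Overlaps and correlations between them were set beside 100 simulations of unchanged groups and beside the overlap of independent lists; 3 controls are too few to be split.

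On simulated data made from the means and spreads of the 15011 intervals in the comparison of shCTDP1-#1 with shScr, the test recovered 38.8% of 67 intervals changed by 1.25-fold, 79.1% of 67 changed by 1.5-fold and 95.5% of 66 changed by 2-fold, with 12 false calls. The changed intervals were drawn only from those with a mean of at least 5 TPM. Recovery among tested intervals at lower level was not measured. Only these few intervals were changed in the simulation, while 63.1% of the tested intervals were called in the data. The Benjamini-Hochberg adjustment is stricter where fewer intervals change, so the recovery and the number of false calls do not carry over to the data. Alternatives covered the pseudocount (0.1 TPM), the filter, the scaling of TPM, a test against a 1.5-fold change (treat), the libraries in the fit, the replicate number as a block, and each library left out in turn. Tables were made with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.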

Results

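The transcriptome of MDA-MB-231 breast cancer cells was profiled in 9 libraries: 3 with the scrambled hairpin shScr, 3 with shCTDP1-#1 and 3 with shCTDP1-#2. Each value is the TPM of 1 genomic interval on hg19, as deposited. The comparisons ask how transcript levels changed when CTDP1 was targeted, and whether both hairpins gave the same change. The intervals carry no gene names, so the level of CTDP1 in these libraries is not reported and the nuclear intervals are described by position.

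More intervals had a value above 0 in the knockdown libraries. The shScr libraries listed 19764 ± 266 such intervals (mean ± SD, n = 3), the shCTDP1-#1 libraries 22170 ± 298 and the shCTDP1-#2 libraries 21844 ± 265. Every knockdown library lay above every shScr library. The exact two-sided permutation test gave p = 0.1 for either hairpin, the smallest that 3 against 3 libraries allow. At 1 TPM or more, the counts were 13682 ± 62 with shScr, 14433 ± 74 with shCTDP1-#1 and 14646 ± 90 with shCTDP1-#2. Across the tested nuclear intervals, log2 values correlated at 0.988 to 0.990 between libraries of a group and at 0.947 to 0.971 between groups; these correlations are across intervals, which are not independent replicates. 1 library stood apart in its mitochondrial share. Mitochondrial intervals took 4.47% of the TPM in shScr replicate 1, against 1.12% and 1.66% in shScr replicates 2 and 3.

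**Figure D1:**
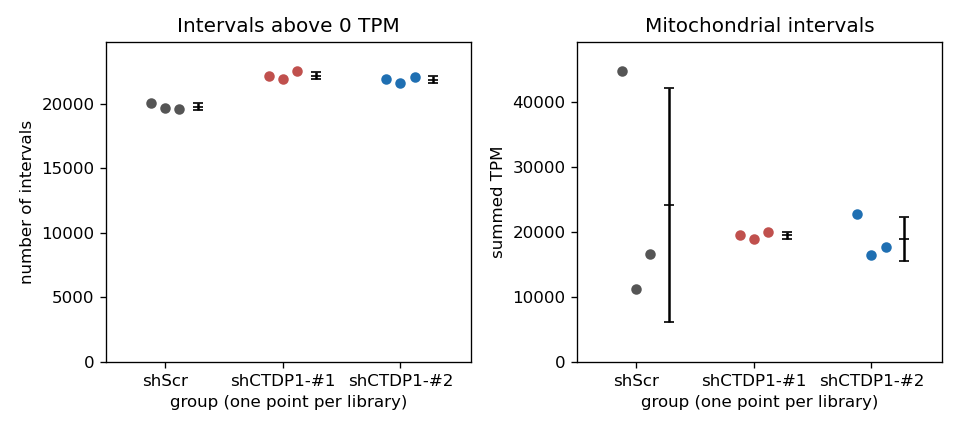
Number of intervals above 0 TPM (left) and summed TPM of the mitochondrial intervals (right) in each library, with the group mean ± SD beside the points. All 6 knockdown libraries list more intervals than the 3 shScr libraries, and shScr replicate 1 holds the highest mitochondrial sum, 44723 TPM.

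With shCTDP1-#1, 5314 intervals rose and 4161 fell against shScr, which together is 63.1% of the 15011 tested. The interval on chromosome 2 from 8818975 to 8824583 rose from 1.53 ± 0.37 TPM (SD, n = 3) with shScr to 81.9 ± 1.8 TPM. The interval on chromosome 19 from 56270380 to 56274541 rose from 0.467 ± 0.163 to 42.0 ± 3.5 TPM. An interval on an alternate sequence of chromosome 17 (HSCHR17_4_CTG4, 39215722 to 39216596) fell from 55.7 ± 6.2 to 5.39 ± 1.15 TPM. On chromosome 17 itself, the interval from 38171614 to 38174066 fell from 72.4 ± 0.2 to 10.6 ± 1.8 TPM. The log2 changes of these 4 intervals, in the same order, were 5.05 (SE 0.10), 4.88 (SE 0.12), -3.16 (SE 0.15) and -2.67 (SE 0.10), with limma adjusted p-values of 2.5e-10, 7.4e-10, 5.3e-08 and 1.2e-08. With a pseudocount of 0.1 TPM, the chromosome 19 interval had the larger log2 change of the first pair, 6.26 against 5.68. All 3 knockdown libraries showed each of these directions, as the rule that chose the intervals required. Off the X and Y chromosomes, 2884 risen and 2093 fallen intervals met that rule, and the printed ones ranked first in their direction. Reads of the interval on the alternate sequence, and of any interval with a near-identical copy, can be divided between copies, so those levels are uncertain.

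Most of the called changes with shCTDP1-#1 were modest in size. The median absolute log2 change of the called intervals was 0.57, against a median SE of 0.095. Changes of at least 1 on the log2 scale were seen in 1084 intervals that rose and 630 that fell. The median over all tested intervals was 0.07. Tested against a fold change of 1.5, 1184 intervals were higher and 873 lower.

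With shCTDP1-#2, 5923 intervals rose and 3689 fell, 64.0% of those tested. The same 4 intervals moved in the same directions, which the rule that chose them required, so this is no separate evidence of agreement. The intervals on chromosomes 2 and 19 reached 65.2 ± 4.0 and 25.6 ± 3.4 TPM, with log2 changes of 4.72 (SE 0.10, limma adjusted p = 3.4e-10) and 4.18 (SE 0.12, adjusted p = 2.2e-09). With a pseudocount of 0.1 TPM these changes were 5.35 and 5.54, so their order turned here too. The interval on the alternate sequence of chromosome 17 dropped to 4.20 ± 0.81 TPM, a log2 change of -3.45 (SE 0.15, adjusted p = 3.4e-08), and the interval on chromosome 17 itself to 13 ± 0.9 TPM, a log2 change of -2.39 (SE 0.10, adjusted p = 3.0e-08). Changes of at least 1 on the log2 scale were seen in 1267 intervals that rose and 347 that fell. Against a fold change of 1.5, 1429 intervals were higher and 576 lower.

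The balance of higher and lower calls varied with the scaling. With TPM as deposited, 56.1% of the calls with shCTDP1-#1 and 61.6% of those with shCTDP1-#2 were higher, and the median log2 change over all tested intervals with shCTDP1-#2 was 0.13. After upper-quartile scaling 55.3% and 55.7% were higher, and the median with shCTDP1-#2 was 0.07. After median-of-ratios scaling 51.0% and 50.3% were higher; that scaling centres the changes near 0, so a nearly even balance follows from it and does not show where an excess came from.

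**Figure D2:**
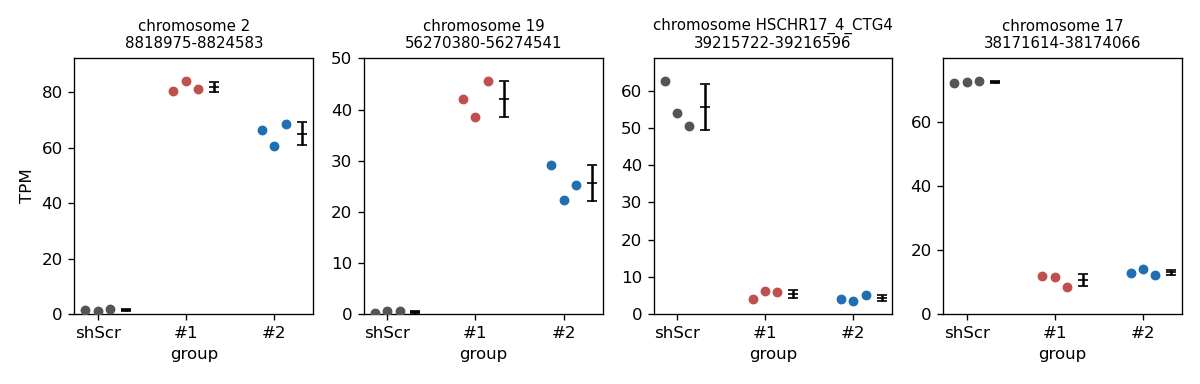
TPM of the 4 printed intervals in each library (points) with the group mean ± SD, on linear axes that start at 0; #1 and #2 are the hairpins against CTDP1. The intervals on chromosomes 2 and 19 are near 0 TPM with shScr and reach 65.2 and 25.6 TPM with shCTDP1-#2, while both intervals assigned to chromosome 17 fall with both hairpins.

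Both hairpins together moved 3956 intervals up and 2475 down in the same direction. After upper-quartile scaling 3677 went up and 2752 down, and after the centring median-of-ratios scaling 3282 and 3156. Among those called with TPM as deposited, 663 rose and 156 fell by at least 1 on the log2 scale with each hairpin. A further 815 intervals were called with both hairpins in opposite directions, 335 of them higher with shCTDP1-#1 and 480 higher with shCTDP1-#2. Independent lists of these lengths would share 2097 higher and 1023 lower intervals. The 335 and 480 intervals called in opposite directions are each fewer than independent lists would share in that way. Groups simulated as unchanged, with their shared controls simulated too, shared 0 higher and 0 lower calls in 100 simulations. Unchanged groups give almost no calls, so that outcome was set beforehand. It does not gauge how much overlap shared controls add among changed intervals.

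Across intervals, the fold changes of both hairpins correlated at r = 0.746, and 75.9% had the same sign. Simulated unchanged groups that share 3 simulated controls gave a mean r of 0.498 and 66.6% with the same sign. Values near these follow from groups of equal size with shared controls and no change, so both were set beforehand. They do not give the part of the observed r that the shared controls account for. The covariance was 0.318, against 0.0148 in the simulations, a difference of 0.303. The spread between libraries in the shared controls therefore accounted for little of the covariance. Any trait common to the 3 shScr libraries enters both comparisons and is not in the simulations. Part of the overlap beyond independent lists may thus still come from the shared controls, which cannot be split.

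**Figure D3:**
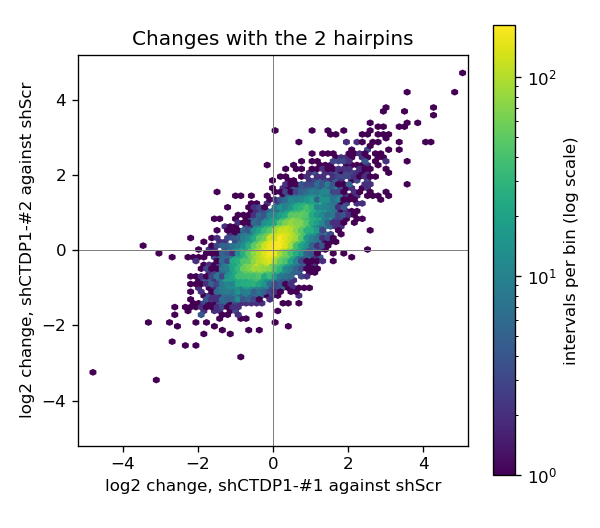
log2 change of each tested interval with shCTDP1-#1 (horizontal) and shCTDP1-#2 (vertical) against shScr, coloured by the number of intervals per bin on a log scale; intervals of the Y chromosome are left out. The cloud lies along the diagonal, with r = 0.746.

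The hairpins also differed from each other. In shCTDP1-#2 against shCTDP1-#1, 4535 intervals were higher and 3003 lower, 50.2% of those tested. After upper-quartile scaling 3858 were higher and 3612 lower, and after the centring median-of-ratios scaling 3754 and 3676. These differences were smaller than those against shScr: the median absolute log2 difference of the called intervals was 0.46, and 377 were higher and 207 lower by at least 1 on the log2 scale. Of the called changes against shScr, 1615 were called with shCTDP1-#1, not with shCTDP1-#2, and also differed between the hairpins. For shCTDP1-#2 that number was 1703. Tested against a fold change of 1.5, 426 intervals were higher and 237 lower with shCTDP1-#2.

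The mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, were the 1 planned list that could be tested. None of the 13 mRNAs passed the limma test with either hairpin, over all intervals or adjusted over the list alone, and 0 had an unadjusted p under 0.05. MT-CO1, a core subunit of cytochrome c oxidase, was at 3253, 821 and 1298 TPM in the 3 shScr libraries and between 1100 and 1565 TPM in the knockdown libraries. MT-ND1, a subunit of complex I, had log2 changes of -0.34 (adjusted p = 0.59) and -0.38 (adjusted p = 0.54) with the hairpins. The median log2 change of the list was -0.06 with shCTDP1-#1 (camera adjusted p = 0.652) and -0.26 with shCTDP1-#2 (camera adjusted p = 0.231). With an estimated correlation the adjusted p was 0.898 with shCTDP1-#1 and 0.736 with shCTDP1-#2. The fry test, which asks whether the members move one way on balance, gave an adjusted p of 0.941 and 0.709. Between the hairpins the camera adjusted p was 0.334, and 0.785 with an estimated correlation. The list's direction rested on shScr replicate 1: without it, camera placed the list higher with shCTDP1-#1 (camera adjusted p = 0.0473) and with shCTDP1-#2 (camera adjusted p = 0.268). Without shScr replicate 2, camera placed the list lower with shCTDP1-#2 (camera adjusted p = 0.0108). These values are not adjusted over the libraries left out in turn. They rest on the preset correlation of 0.01, while the estimated correlation of the list in all 9 libraries was 0.989. With an estimated correlation, the camera adjusted p without shScr replicate 1 was 0.573 with shCTDP1-#1 and 0.75 with shCTDP1-#2. Without shScr replicate 2 it was 0.485 with shCTDP1-#2.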

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

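The tests of the splits and of the value of a read in this part were chosen after the results were seen; the test of the scaling was written down before its result was known, but was tied to the number at 1 TPM or more only afterwards. The results below stand out because the change against shScr differed between the hairpins in a test of the difference itself. The level of CTDP1 was not analysed, so its part in that difference was not tested. With shCTDP1-#2, 4535 intervals were higher and 3003 lower than with shCTDP1-#1, and 815 intervals were called in opposite directions against shScr. Those 815 are fewer than independent lists of the same lengths would share in opposite directions. After upper-quartile scaling 3858 were higher and 3612 lower between the hairpins, and after median-of-ratios scaling, which centres the changes near 0, 3754 and 3676.

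For shCTDP1-#1 against shScr, 1 of the 10 splits of the 6 libraries gave as many calls, the real one, with 9475 calls; the highest other split gave 1. For shCTDP1-#2 against shScr the real split gave 9612 calls and the highest other 1, and between the hairpins the real split gave 7538 and the highest other 1, again 1 of 10 splits each. With 10 splits the share cannot fall under 0.05. For calls in the same direction with both hairpins, 1 of 100 splits of the 9 libraries gave as many, the real one, with 6431 calls. The highest other split gave 4815 and kept 1 of the study's groups whole; the 93 splits that kept none whole gave at most 1. That share shows that the groups of libraries differ, as the higher correlations within groups had already shown. A split that mixes the groups widens the spread within its parts, so few calls there follow from that difference. The share says nothing of the spread between cultures, since the libraries of a group may be technical replicates.

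More intervals had a value above 0 TPM in all 6 knockdown libraries than in any shScr library. Deeper sequencing of the knockdown libraries would make 1 read worth less TPM there; that worth was read from the peak in the ratios of low values of intervals shorter than 700 bases. It was lower than in shScr replicate 1, the shScr library where it was lowest, in 0 of 6 knockdown libraries, and log2 ratios to that library ran from 0.09 to 0.30. The groups overlapped in this measure, at 0.08 and 0.19 in shScr replicates 2 and 3, and 2 knockdown libraries lay below shScr replicate 3. The peaks rest on 118 to 168 ratios for each library set against shScr replicate 1. An untested difference in fragment length could shift the values of short intervals, so the measure does not exclude deeper sequencing. A scaling factor applied to the deposited values cannot change the number above 0 TPM. Since these values carry 2 decimals, scaling before they were cut to that length could have changed it. For the number at 1 TPM or more, which was also higher in the knockdown libraries, scaling is argued against as the whole cause: after median-of-ratios scaling the lowest knockdown library had 560 more such intervals than the highest shScr library. A change brought by targeting CTDP1, and an untested difference in fragment length or RNA preparation between the groups, may each account for the rest.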

How the results depend on the processing

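The alternatives of the filter, the scaling, the 1.5-fold test, the sequences left out, and the estimated correlation with a library left out were chosen after seeing the data; the others were planned. Every count of changed intervals stayed within 1.5 times its main value except under the test against a fold change of 1.5. That test gave 1184 higher and 873 lower with shCTDP1-#1, 1429 and 576 with shCTDP1-#2, 426 and 237 between the hairpins, and 759 and 265 in the same direction with both, since it asks for a larger change. Leaving out each library in turn gave 4788 to 5275 higher and 3791 to 4166 lower with shCTDP1-#1, 5427 to 5870 and 3324 to 3696 with shCTDP1-#2, 4011 to 4540 and 2622 to 2985 between the hairpins, and 3643 to 3842 and 2171 to 2420 with both; r ran from 0.738 to 0.751. The p of the mitochondrial list ran from 0.0473 to 0.699 with shCTDP1-#1 and from 0.0108 to 0.362 with shCTDP1-#2. Without shScr replicate 1 its direction turned to higher with both (camera adjusted p = 0.0473 and 0.268). Without shScr replicate 2 the list was lower with shCTDP1-#2 at a camera adjusted p of 0.0108. The high mitochondrial share of replicate 1 leaves the shScr mean in the first case and weighs more in it in the second. These p-values rest on the preset correlation and are not adjusted over the libraries left out in turn. With an estimated correlation the adjusted p without shScr replicate 1 was 0.573 and 0.75, and without shScr replicate 2 it was 0.485 with shCTDP1-#2. The 4 printed intervals kept their direction and stayed past the threshold in the alternatives run, except that leaving out alternate sequences removes 1 of them, on HSCHR17_4_CTG4. Median-of-ratios scaling, by its centring, made higher and lower calls nearly even (4829 and 4648 with shCTDP1-#1).

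Replicate numbers recur in each group. Residuals of same-numbered libraries of different groups correlated at -0.01 to 0.05, and those of other-numbered ones at -0.05 to 0.02. These ranges overlap. Of the 9 libraries, 8 correlated best with their own number, a hint from the data, not from the design. Those matches are not independent of each other, since each correlation counts for both of its libraries. With the replicate number as a block (the replicate block), 5279 were higher and 4114 lower with shCTDP1-#1, 5881 and 3636 with shCTDP1-#2, 4470 and 2955 between the hairpins, and 3909 and 2438 with both, and r was unchanged at 0.746; 9393, 9517 and 7425 intervals were called in the 3 comparisons, of which 9212, 9344 and 7239 were also called without it. The planned count-based tests, normalization factors and rounding were not run, as the files hold TPM; CTDP1, the named genes and the other lists were not analysed here. Depth is unknown, so the precision of low values cannot be stated.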

Other observations

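The tests of neighbouring intervals were chosen after their values were seen, and the chromosomes and the classes of level and span after the data were seen; both tests on level classes were written down before their results were known. Risen and fallen intervals were found on every autosome and on X with both hairpins. With camera, 0 of 23 chromosomes (the autosomes and X) stood apart from the rest with either hairpin, 0 had an unadjusted p under 0.05, and 0 stood apart with an estimated correlation. The lowest adjusted p was 0.941 with shCTDP1-#1 and 0.986 with shCTDP1-#2. Camera allows for correlation between the members of a list, and that allowance grows with the length of the list. With 137 to 1447 tested intervals per chromosome it left little power, so these tests do not show an even spread. On chromosome 19, 1058 intervals were tested. Of these 415 rose and 227 fell with shCTDP1-#1, and 457 rose and 243 fell with shCTDP1-#2. Its median log2 changes were 0.15 and 0.22, against 0.06 and 0.13 over the other intervals.

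Intervals at low level rose more than those at intermediate level. With shCTDP1-#1, the median log2 change was 0.22 in the 1483 intervals with a mean of 1 to 2 TPM and 0.00 in the 2270 with 10 to 20 TPM. With shCTDP1-#2, the medians were 0.25 and 0.08. Intervals with a genomic span of 300 to 1000 bases rose more than those of 30000 to 100000 bases. The medians with shCTDP1-#1 and shCTDP1-#2 were 0.22 and 0.29, against 0.02 and 0.10. The rise was not largest in the shortest class: the 101 intervals under 300 bases had medians of 0.17 and 0.15. With shCTDP1-#2 that was no higher than at 10000 to 30000 bases, 0.15. Level and span were not separated. For the mean log2 change of both hairpins, taken per interval, the difference of medians between the classes of level was 0.21. A filter that rising intervals pass more easily is argued against as the whole cause, since the difference was still 0.178 with no filter and groups weighted alike. Reads of overlapping intervals are argued against as the whole cause, since it was 0.221 in intervals that overlap no other. A candidate explanation that stays open is a broad gain of weakly expressed transcripts after CTDP1 was targeted. Depth is unknown, so a difference in depth between the groups stays open too. A difference in RNA preparation between the groups was not tested.

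Neighbouring intervals changed alike to a small degree. For intervals next to each other and 1 to 5000 bases apart, r was 0.0950 with shCTDP1-#1 and 0.117 with shCTDP1-#2, above the highest of 1000 shuffled orders within chromosomes (0.0593 and 0.0610). For pairs more than 100000 bases apart, r was 0.0285 and 0.0329, below the highest of the shuffled orders. Reads shared by overlapping intervals are argued against as the whole cause, since the pairs with a gap do not overlap. Nor was r higher in the overlapping pairs than in those 1 to 5000 bases apart. What else makes neighbours change alike was not tested.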
